A study of Mus musculus with 8 samples.

How the data were processed

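Small RNA was sequenced from Kupffer cells, the resident macrophages of the liver, which had been isolated by flow cytometric sorting from male mice. Per the labels, 4 libraries came from wild-type animals and 4 from Trem2 knockout animals, each a separately numbered mouse, and each library was built from 1 µg of total RNA with the Illumina TruSeq small RNA kit. The mice started a high-fat diet at 8 weeks of age and stayed on it for 8 weeks, and the wild-type mice were littermates of the knockouts. The read trimming, the aligner, the miRNA database and the genome build are not given in the sources used here.

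The deposited table listed 1234 entries with 1193 different sequences. Of these, 565 carried mouse miRNA names, 398 carried names from other species and 271 carried names of predicted small RNAs beginning with PC. Numbers in the running index left 2 positions without an entry, which were not analysed here. Suffixes in the deposited entry names were left out of the names printed here unless they were needed to tell entries apart. Of the sequences, 40 were shared by 81 entries, among them let-7a-5p and an entry named as a variant of let-7c-5p, so the values of such entries are uncertain as to their source.

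The deposited raw columns held expected counts, per the file headers and the values: 12.0% of the values were not whole within a tolerance of 1e-06, as would arise if a read were divided among several entries. The deposited normalized columns held a signal that equalled the raw value multiplied by 1 constant factor per library. That factor multiplied by a median-of-ratios size factor computed from the raw columns gave 0.970 to 1.04 over the 8 libraries. No sequence length entered the values, so they were treated as scaled counts and not as FPKM. The table was assumed before the data were examined to hold either normalized values or raw counts, with a test fixed for each case, and the test for counts was used. The expected counts were rounded to whole numbers before any count model.

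Total expected counts per library ranged from 2129942 to 9443992. At these depths 3 counts corresponded to 0.318 to 1.41 CPM (the count divided by the library's total and scaled to a total of 1e6). Reads carried no molecular identifiers in the columns used, so Wilson intervals (95%) for a share of counts cover counting error only.

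Entries were filtered with filterByExpr of edgeR, which left 627. Library scaling used TMM factors, and knockout was compared with wild type by the edgeR quasi-likelihood test with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Group levels are TMM-scaled CPM with the SD over 4 libraries. Standard errors of log2 differences were derived from the quasi-likelihood F statistic. For miR-106b-5p an exact two-sided permutation test over the 70 assignments of 8 libraries to 2 groups of 4 was added, whose smallest possible p is 0.0286.

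The choice of 21 miRNA lists was fixed before the data were examined, and 19 had at least 3 tested members. The miR-34 family had 1 tested member and the Sfmbt2 cluster had 0, so neither was tested. Lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Cell type lists name miRNAs enriched in a cell type, not exclusive to it, and several members stand in more than 1 list.

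The miRNAs named for the genotype comparison followed a rule fixed before the data were examined. It took up to 12 miRNAs each way past the threshold and, because fewer than 10 passed, the 8 with the smallest unadjusted p in each direction, all arms of the miR-106b~25 cluster, the 10 most abundant entries, 2 to 4 members with the smallest p in each list and the 2 most abundant members of each cell type list. Within that 2 to 4, 3 members per list were used throughout. A count of 2 per list was tried once after the sensitivity results had been seen, and it lowered the number of reversed values. It was discarded for that reason and the first choice of 3 was restored. The miRNAs named for the comparison of animal number ranges were chosen after their values were seen, from mouse entries past the threshold with a mean of at least 100 CPM. The text names only part of those that each rule selected.

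Alternatives planned before the data were examined were no filter, a filter of 10 counts in 4 libraries, DESeq2 size factors, quantile normalization, voom with quality weights, a block for the range of the animal numbers (35 to 46 against 80 to 90, with 2 wild-type and 2 knockout mice in each), leaving out each library, DESeq2, an adjusted p of 0.1, 1 entry per mature name, and for the lists an estimated correlation, fry and removal of members with a mean count under 10. The labels do not say that the number range is a batch. Alternatives added after seeing the data were limma-trend on log2 of the deposited normalized value plus 1, identical sequences merged, mouse entries only, CPM without TMM factors, each number range alone (for the lists also with an estimated correlation), and an exact permutation of genotype within the number ranges for miR-106b-5p. The fits that compared the number ranges with each other, and their corrections for GC content and length, for the first and last 2 bases, and for depth, the test of the 2 most abundant members of each cell type list, leaving out each library in these fits, and the counts of separating entries over splits balanced for number range, were also added after seeing the data. A first form of the cell type test kept 2 markers that also stand in the myeloid list, and it was replaced by a form without them. Both markers were called lower in animals 35 to 46. The replacement therefore turned the outcome from against a different share of Kupffer cells to undecided.

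Scripts were tested on simulated counts for the 627 entries of the genotype comparison, with 200 entries changed. Of entries changed 2-fold, 0% were recovered without the block and 15% with it. Of entries changed 4-fold, 23% were recovered without the block and 58% with it. False calls numbered 0 without the block and 7 with it, and data with no change gave 0 calls.

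Named sequences were matched without mismatches to 2202 miRNA transcripts of GENCODE M21 (GRCm38), and 82 of 102 matched. Coordinates are 1-based on GRCm38 and come from this match, since the authors' build is not given in the sources used here. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Trem2 mRNA was not analysed here, so the genotype labels were not checked against the targeted gene.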

Results

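Small RNA libraries were examined from Kupffer cells of mice lacking Trem2, a lipid-sensing receptor of macrophages, and of their wild-type littermates after a high-fat diet that models fatty liver. There were 4 wild-type libraries (animals 35, 37, 80 and 82) and 4 knockout libraries (animals 40, 46, 88 and 90). Total counts were 2573618, 2830978, 9443992 and 3873066 in wild-type libraries 35, 37, 80 and 82. They were 3809016, 2129942, 2607271 and 6465609 in knockout libraries 40, 46, 88 and 90. Mouse-named entries took 97.7% to 99.0% of the counts.

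The most abundant miRNA in each of the 8 libraries was miR-21a-5p, an inflammation-associated miRNA. It took from 17.2% of the counts in knockout library 88 (Wilson 95% interval 17.2 to 17.3) to 38.0% in knockout library 40 (38.0 to 38.1). Its sequence, TAGCTTATCAGACTGATGTTGA, lay at chromosome 11, 86584120 to 86584141, on the minus strand within the precursor Mir21a, which overlaps an exon of Vmp1. The level was 266106 ± 91804 CPM in wild-type libraries and 277217 ± 124813 CPM in knockout libraries (SD, n = 4 each). Next in abundance was miR-146a-5p, a feedback regulator of Toll-like receptor signalling, at 84665 ± 29132 CPM in wild type and 82998 ± 11281 CPM in knockout. The myeloid and lymphoid miRNA miR-142a-5p stood at 17846 ± 5586 CPM in wild type and 21548 ± 7293 CPM in knockout. The 10 most abundant miRNAs also included miR-30d-5p, miR-29a-3p, miR-22-3p, miR-191-5p, miR-122-5p, let-7g-5p and let-7f-5p.

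The first comparison asked whether loss of Trem2 altered the miRNA profile of Kupffer cells. No individual miRNA rose or fell past the threshold. Of 627 entries, 0 passed an adjusted p of 0.05 in edgeR, and 2 had an unadjusted p under 0.05, against 31.35 expected by chance. Differences between the animal number ranges stayed in the spread of this fit. Its common dispersion was 0.582, against 0.276 with the number range block, so its p values and intervals are conservative. The miRNA with the lowest p among mouse entries was miR-541-5p, of the imprinted Dlk1-Dio3 cluster, at 15.9 ± 19.1 CPM in wild type and 2.28 ± 1.93 CPM in knockout (SD, n = 4 each). Its log2 difference, knockout minus wild type, was -2.78 ± 1.19 (SE), and its edgeR adjusted p was 0.997. Wild-type library 82 held 44.1 CPM against 1.91 to 10.2 CPM in the other wild-type libraries, and without it the miR-541-5p log2 difference was -1.505. Among abundant miRNAs the smallest p belonged to miR-125b-5p, which was 1573 ± 632 CPM in wild type and 970 ± 188 CPM in knockout, a log2 difference of -0.70 ± 0.34 (SE). Here too wild-type library 82 was the highest, at 2480 CPM against 1140 to 1527 CPM, and without it the miR-125b-5p log2 difference was -0.39. The sign of the difference did not rest on that library alone. Within each animal number range, every knockout library lay below every wild-type library for miR-125b-5p. This is no independent support, since miR-125b-5p was picked for its small p in these same libraries. An exact two-sided permutation within the ranges allows no p below 0.0556 over its 36 assignments, so many of the 627 entries could separate by chance. How many other entries do so was not counted. The sequence of miR-125b-5p, TCCCTGAGACCCTAACTTGTGA, matched both Mir125b-1 on chromosome 9 (41581940 to 41581961) and Mir125b-2 on chromosome 16 (77646279 to 77646300), so the counts do not tell the loci apart.

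Further entries with small unadjusted p included several of low level or wide spread. The muscle miRNA miR-1a-3p had a log2 difference of 2.26 ± 1.05 (SE), with a knockout mean of 85.5 ± 116 CPM (SD, n = 4). Knockout library 90 held 258 CPM against 10.3 to 47.0 CPM in the other knockout libraries, and without it the miR-1a-3p log2 difference was 0.63. The erythroid miRNA miR-144-5p was 23.7 ± 8.85 CPM in wild type and 58.9 ± 46.8 CPM in knockout. The epithelial miRNA miR-205-5p was 10.8 ± 5.43 CPM in wild type and 34.2 ± 39.1 CPM in knockout. The Dlk1-Dio3 member miR-376b-3p was 13.1 ± 17.7 CPM in wild type and 0.884 ± 1.77 CPM in knockout. The miRNAs miR-149-5p and miR-351-3p had log2 differences of -1.12 and -1.24. Leaving out 1 library brought the miR-144-5p log2 difference from 1.32 to 0.65 (knockout library 88), the miR-205-5p log2 difference from 1.67 to 0.47 (knockout 40), the miR-376b-3p log2 difference from -3.87 to -2.31 (wild-type 82) and the miR-149-5p log2 difference from -1.12 to -0.60 (wild-type 37). Entries of higher level were also among them: mir-6240-p5 was 451.1 ± 161 CPM in wild type and 283 ± 44.0 CPM in knockout, mir-6240-p3 was 4502 ± 1563 and 2998 ± 386 CPM, and an entry with a pig miRNA name, ssc-mir-1285-p3_1ss24TA, was 2307 ± 1031 and 1436 ± 220.6 CPM. Wild-type library 82 held the highest value of mir-6240-p5 and of ssc-mir-1285-p3_1ss24TA. Without that library the ssc-mir-1285-p3_1ss24TA log2 difference went from -0.68 to -0.37. The sequences of mir-6240-p5, mir-6240-p3 and ssc-mir-1285-p3_1ss24TA matched none of the miRNA transcripts searched without mismatches. Whether they derive from miRNAs or from other RNA was not tested. DESeq2 and limma-trend on the deposited normalized values also gave 0 calls, with 6 and 3 entries at an unadjusted p under 0.05. The number range block gave 0 calls and 17 such entries in edgeR. Each of these counts also lay under the 31.35 expected by chance.

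A second question concerned miR-106b-5p, chosen before the data were examined from knowledge of the study, and the miR-106b~25 cluster that encodes it. The study of these mice centres on miR-106b-5p and may have drawn on these same libraries. The choice may therefore not be independent of them, and the p values below cannot count as independent support. The level of miR-106b-5p was 801.7 ± 75.8 CPM in wild type and 928 ± 96.1 CPM in knockout (SD, n = 4 each), a log2 difference of 0.21 ± 0.25 (SE; 95% interval -0.35 to 0.78). This difference did not pass either test (edgeR adjusted p 0.997, exact two-sided permutation p 0.114 over all assignments). The groups overlapped only across animal number ranges: the lowest knockout and highest wild-type libraries were 905 and 881 CPM in animals 35 to 46, and 824 and 754 CPM in animals 80 to 90. With genotype permuted within the ranges, a test added after seeing the data, the exact two-sided p was 0.0556, the smallest that its 36 assignments allow. In the other direction miR-125b-5p also separated the genotypes within both ranges, and the entries that do so were not counted. On the deposited normalized scale the miR-106b-5p values were 2900 ± 218.3 in wild type and 3459 ± 250 in knockout, a 1.19-fold ratio. There the lowest knockout library, at 3238, lay above the highest wild-type library, at 3191 (exact two-sided permutation p 0.0286, the smallest that 4 against 4 libraries allow). On that scale 6 of the 627 entries separated the groups completely. Among the other splits with 2 libraries of each animal number range on each side, the count was 0 to 27, with a mean of 7.29. Within animals 35 to 46 the log2 difference was 0.24 ± 0.24 (SE), and within animals 80 to 90 it was 0.27 ± 0.26.

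The mature sequence TAAAGTGCTGACAGTGCAGAT lay at chromosome 5, 138165787 to 138165807, on the minus strand in the 82-nucleotide precursor Mir106b (138165737 to 138165818), in an intron of Mcm7. The other cluster precursors, Mir93 (138165523 to 138165610) and Mir25 (138165321 to 138165404), overlapped annotated exons of Mcm7. The cluster did not pass as a list, with 4 of 6 arms higher, 2 lower and 0 called (camera adjusted p 0.853). The log2 difference was 0.12 for miR-25-3p, -0.57 for miR-25-5p, 0.11 for miR-106b-3p, -0.11 for miR-93-5p and 0.02 for miR-93-3p. The signs of miR-25-3p, miR-25-5p, miR-106b-3p, miR-93-5p and miR-93-3p turned under at least 1 other setting.

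**Figure D1:**
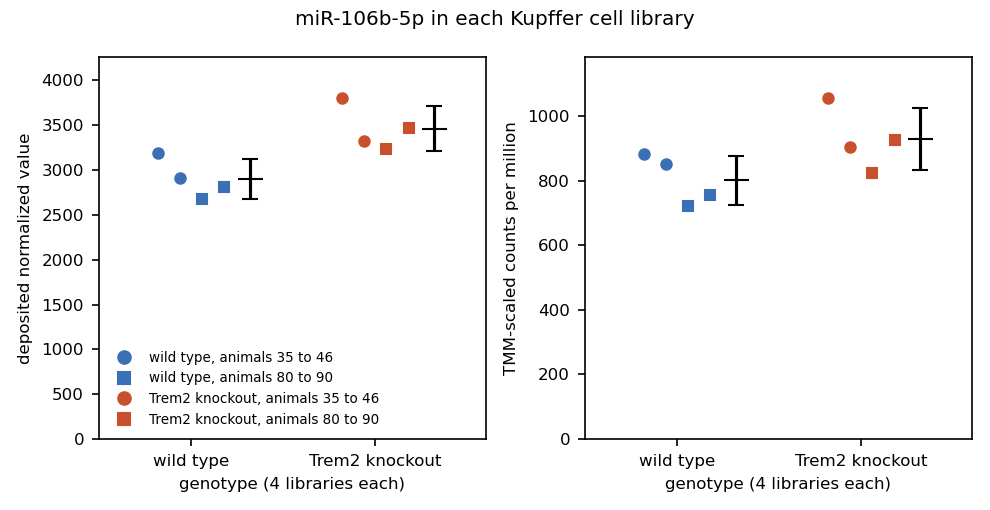
miR-106b-5p in each of the 8 libraries, on the deposited normalized scale (left) and as TMM-scaled CPM (right), by genotype. Each point is 1 library, the shape gives the animal number range, and the black mark and bar give the mean and SD of 4 libraries. On the left the lowest knockout library (3238) lies above the highest wild-type library (3191), and on the right the groups overlap.

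The lists addressed whether miRNAs of related function or cellular origin differed as groups. Hepatocyte-enriched miRNAs were lower in knockout libraries as a list, and 1 of 19 lists passed. Of 11 members 9 were lower and 2 higher, with a median log2 difference of -0.76 (camera adjusted p 0.0108), and 0 members were called over all entries or adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.776 with an estimated correlation). The liver-specific miR-122-5p, from Mir122 at chromosome 18, 65248861 to 65248926, was 34762 ± 53912 CPM in wild type and 14139 ± 12465 CPM in knockout (SD, n = 4 each). The wild-type mean rested on library 37, where miR-122-5p reached 115597 CPM, 14.8 times the mean of the other wild-type libraries. In the same library miR-192-5p stood 5.85 times, miR-194-5p_R+1 3.55 times and miR-148a-3p 7.63 times above that mean. Without wild-type library 37 the list's median log2 difference was 0.19 (camera adjusted p 0.865), and without knockout library 46 it was -0.53 (camera adjusted p 0.197).

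**Figure D2:**
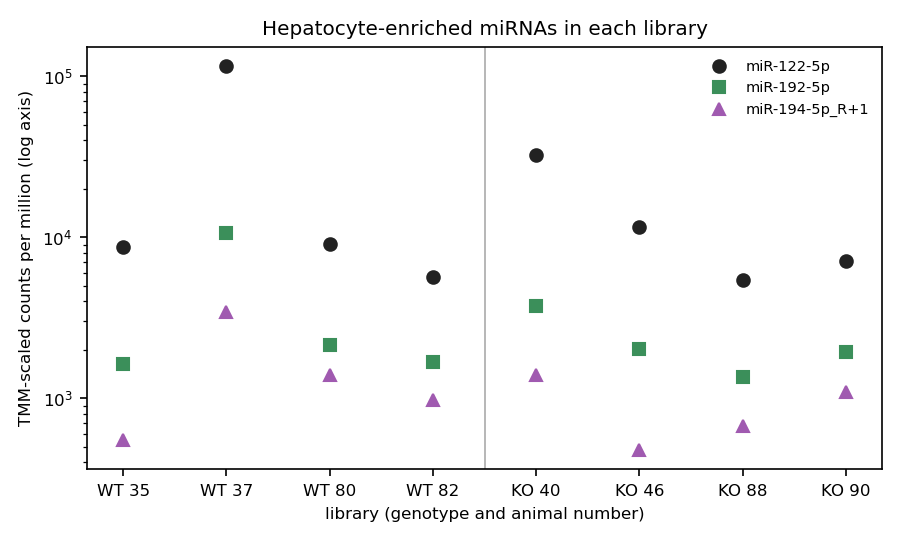
TMM-scaled CPM (log axis) of the hepatocyte-enriched miR-122-5p, miR-192-5p and miR-194-5p_R+1 in each library, wild type left of the line and knockout right of it, 1 point per library. Wild-type library 37 holds the highest value of each miRNA, with miR-122-5p at 115597.

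The remaining 18 lists did not pass over the 8 libraries. Of miRNAs induced by Toll-like receptor or NF-kB signalling, 12 of 16 were lower (median log2 difference -0.21, adjusted p 0.204), including miR-155-5p at -0.55 ± 0.52 and miR-221-5p at -0.55 ± 0.45 (SE). Of miRNAs reported to promote M1 polarization, 4 of 5 were lower (median -0.50, adjusted p 0.204), among them miR-125b-5p and miR-155-5p. Of miRNAs reported to promote M2 polarization, 10 of 17 were higher (median 0.07, adjusted p 0.658). Of the miR-17~92 cluster and its paralogue from miR-106a to miR-363, 10 of 11 arms were lower (median -0.35, adjusted p 0.204), with miR-363-3p at -0.87 ± 0.60 and miR-19a-3p at -0.67 ± 0.60 (SE). Of the let-7 family, 15 of 20 entries were higher (median 0.20, adjusted p 0.543). Among them let-7a-5p and let-7c-5p_1ss19GA share 1 sequence and its values, so the same reads count under both names. The entry let-7c-5p_1ss19GA also stands in the M2 list. Myeloid-enriched miRNAs had 12 of 21 members higher (median 0.05, adjusted p 0.820), with miR-27a-3p at 0.21 ± 0.26 (SE). Lipid and cholesterol metabolism miRNAs had 14 of 25 lower (median -0.04, adjusted p 0.658), though camera placed the list upward. Hypoxia and mitochondrial miRNAs had 9 of 15 lower (median -0.10, adjusted p 0.853), while their mean was 0.12. The fibrosis-related miR-29 and miR-30 families had 11 of 18 lower (median -0.04, adjusted p 0.853), though camera placed them upward. The Dlk1-Dio3 cluster had 10 of 19 lower (median -0.12, adjusted p 0.302). No member of these lists was called, over all entries or adjusted over the list alone.

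Lists for other cell types that a Kupffer cell sort could carry did not pass either, apart from the hepatocyte list. The endothelial list had 5 of 7 lower (median -0.16, adjusted p 0.300), and its most abundant member miR-126a-3p was 13525 ± 1386 CPM in wild type and 11026 ± 1571 CPM in knockout (SD, n = 4 each). The epithelial list had 7 of 7 lower (median -0.29, adjusted p 0.239). The erythroid list had 3 of 5 higher (median 0.02, adjusted p 0.204), with miR-451a at 2882 ± 3029 CPM in wild type and 2459 ± 1918 CPM in knockout. The muscle list had 3 of 4 higher (median 0.60, adjusted p 0.204). The stellate or mesenchymal list had 6 of 11 higher (median 0.00, adjusted p 0.474), with a mean of -0.15 and a downward camera direction. Its lower members miR-199a-5p and miR-199b-5p had identical values. The lymphocyte list had 8 of 13 lower (median -0.13, adjusted p 0.658). The neutrophil or monocyte list had 4 of 6 higher (median 0.04, adjusted p 0.945), with miR-223-3p at 4595 ± 2018 CPM in wild type and 4825 ± 2108 CPM in knockout.

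**Figure D3:**
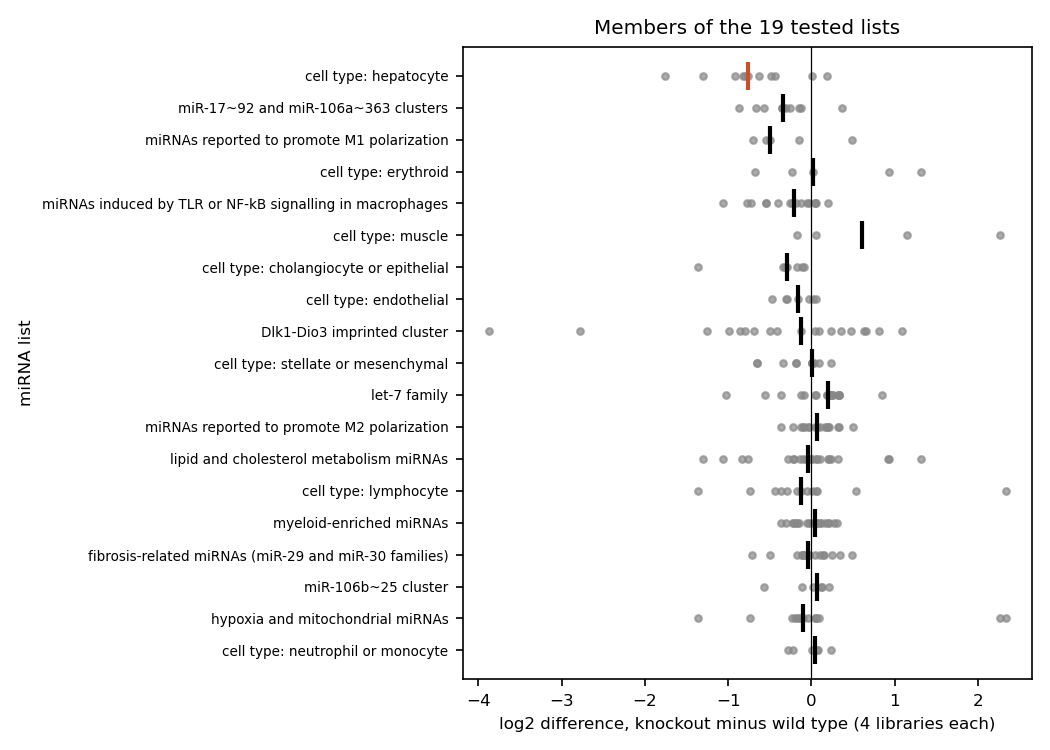
Log2 difference, knockout minus wild type, of each member (grey points) of the 19 tested lists, with the list's median as a vertical mark, red where the camera adjusted p was under 0.05. The hepatocyte list, at a median of -0.76, carries the red mark.

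The libraries grouped by animal number and not by genotype. The first principal component held 52.7% of the variance and separated animals 35 to 46 from animals 80 to 90, each range with 2 wild-type and 2 knockout mice. The mean correlation across entries between libraries was 0.943 within a range and genotype and 0.942 within a range across genotypes. Between ranges it was 0.863 within a genotype and 0.861 across genotypes, and entries are not independent replicates. Between genotypes within each range, edgeR called 0 of 576 entries in animals 35 to 46 and 0 of 755 in animals 80 to 90. The hepatocyte list's median was -1.03 in animals 35 to 46 (camera adjusted p 0.0384; adjusted p = 0.747 with an estimated correlation), where library 37 is 1 of 2 wild-type libraries. It was -0.20 in animals 80 to 90 (camera adjusted p 0.375). In animals 80 to 90 alone, 3 other lists passed camera: M1 polarization (median -0.95, adjusted p 0.000771), Toll-like receptor or NF-kB signalling (-0.39, 0.00851) and erythroid (1.61, 0.00442). None of the 3 calls held with an estimated correlation (adjusted p = 0.834, 0.913 and 0.834). The interaction of genotype with range was called for 0 of 627 entries in edgeR, with 30 at an unadjusted p under 0.05.

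**Figure D4:**
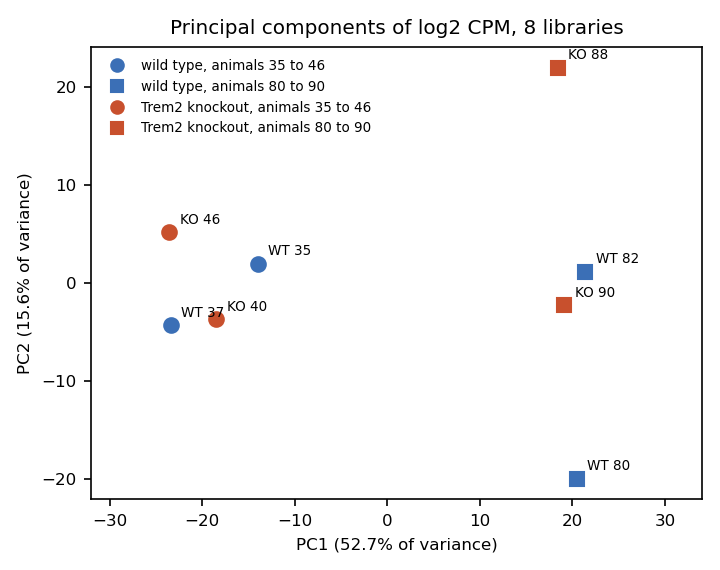
First and second principal components of log2 CPM over 627 entries, 1 point per library, with colour for genotype and shape for animal number range. Animals 35 to 46 lie left and animals 80 to 90 right along the first component (52.7% of the variance), and both genotypes occur on each side.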

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

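The tests of correlation among list members, of scaling, of the cluster transcript and within number ranges were chosen only after the result each concerns had been seen. Single libraries lay far from the other libraries of their genotype in 10 of 164 groups examined on the log2 scale, against 8.2 expected by chance if the libraries of a genotype vary alike.

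In wild-type library 37, miR-122-5p was 116000 CPM against 5636 to 9053 in the other wild-type libraries, and miR-192-5p was 10600 CPM against 1626 to 2146. The hepatocyte list was lower in knockout libraries by a median log2 difference of -0.76, and RNA from hepatocytes in that library, despite the sort, may account for it: without library 37 the adjusted p was 0.8647 and the median 0.19. With an estimated correlation among the members the adjusted p was 0.7757. Chance could not be excluded, since 27 of the 35 splits of the 8 libraries passed as many lists as the real 1, with 9 the highest of the others. That count covers any list. For the hepatocyte list itself, 6 of the 35 splits, the real one included, gave a camera p as low as the real one. A difference in hepatocyte RNA between genotypes stays open as untested beyond these 4 libraries each.

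Of the miR-106b~25 cluster, miR-106b-3p in wild-type library 35 was 452 CPM against 336.8 to 352.7 in the other wild-type libraries. The higher miR-106b-5p of knockout libraries was complete in 2 of 5 scalings, so the complete separation depended on scaling. The log2 difference was 0.21 at the lowest of the 5 scalings and 0.25 on the deposited scale. That argues against the choice among these 5 scalings as the whole cause of the difference. All 5 are computed from the same counts, so a distortion that they share would not be seen. In edgeR the difference also lay within its standard error (0.21 ± 0.25). Variation between mice stays open, as does a small biological difference. For TMM-scaled CPM the exact two-sided permutation p was 0.114 over all assignments and 0.0556 within the number ranges, the smallest possible there. A rise of the whole cluster transcript stays open as well: the other arms had a median log2 difference of 0.02008 with an SD of 0.289, which does not decide it.

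The other single libraries were as follows. In wild-type library 82, miR-146a-5p was 41100 CPM against 97240 to 102590, and miR-10a-5p was 6790 CPM against 12745 to 14285. In knockout library 90, miR-222-3p was 1170 CPM against 770 to 792. In knockout library 46, miR-155-5p was 18.5 CPM against 35.7 to 38.7. In knockout library 40, miR-125a-3p was 4.22 CPM against 12.5 to 14.5. In knockout library 88, miR-376b-3p was 3.54 CPM where the other knockout libraries had 0, and miR-152-5p was 0 CPM against 8.12 to 11.4.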

How the results depend on the processing

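No paired analysis was possible because the labels do not give the litter of each mouse or any other pairing of the genotypes. The count of 0 called miRNAs held under each alternative run, planned and added, and miR-106b-5p stayed higher in knockout in the alternatives run for it, with log2 differences of 0.15 to 0.30 and no model p under 0.05. Its exact permutation p was 0.0286 on the deposited and the quantile-normalized scales. Alternatives on or within the number ranges and limma-trend on deposited values were chosen after seeing the data. The planned pseudocounts and limma without a trend were for normalized values and were not run. Lists past the threshold numbered 3 with no filter (hepatocyte, M1 polarization and muscle) and 3 in animals 80 to 90 (M1 polarization, Toll-like receptor or NF-kB, and erythroid). They numbered 0 with voom quality weights, with fry, and with an estimated correlation over the 8 libraries or in either range. With 1 library left out they numbered 0 to 3. Besides the hepatocyte list, muscle passed without wild-type library 35, let-7 without wild-type 80, Toll-like receptor or NF-kB without wild-type 82, and Dlk1-Dio3 and muscle without knockout 88. The hepatocyte median was -0.38 with voom quality weights, -0.36 with quantile normalization, -0.41 with limma-trend on deposited values, -0.76 with an estimated correlation and with fry, -0.20 in animals 80 to 90 and -1.03 in animals 35 to 46 with either the preset or an estimated correlation, and -1.05 to 0.19 with 1 library left out. Over 81 miRNAs named by the rule, 1347 of 1450 comparisons kept their sign, the others turned and 0 passed the threshold. For 55 of the 81, leaving out 1 library brought the log2 difference under 0.5 times its size or past 0. In animals 35 to 46 the log2 differences that turned were miR-144-5p -0.11, miR-25-5p 0.15, miR-93-5p 0.32, miR-30d-5p 0.26, miR-29a-3p 0.10, miR-22-3p 0.0017, let-7d-3p 0.074, miR-222-3p 0.086, miR-127-3p 0.070, miR-144-3p -0.044, miR-128-3p 0.056, miR-29b-2-5p 0.43, miR-181c-3p 0.14, miR-532-3p 0.34, miR-223-5p 0.30, miR-486a-5p -0.16 and miR-181a-5p 0.074. In animals 80 to 90 they were miR-25-3p -0.045, miR-106b-3p -0.15, miR-93-3p -0.20, miR-21a-5p -0.12, miR-146a-5p 0.24, miR-22-3p 0.062 and miR-451a 1.61. With voom quality weights they were miR-93-5p 0.068, miR-30d-5p 0.031, miR-191-5p 0.063, miR-532-3p 0.16, miR-223-5p 0.091 and miR-486a-5p -0.16, with quantile normalization miR-93-5p 0.0024, miR-146a-5p 0.30, miR-29a-3p 0.074, miR-22-3p 0.0027, miR-451a 0.71 and miR-181a-5p 0.019, with no filter miR-93-3p -0.036 and with the number range block miR-451a 0.57. With DESeq2 size factors and with DESeq2 they were miR-146a-5p 0.014, miR-22-3p 0.025 and miR-29a-3p 0.0071 and 0.0070 in turn, and with limma-trend miR-146a-5p 0.095, miR-29a-3p 0.030, miR-22-3p 0.045 and miR-451a 0.56. With 1 library left out the ranges were miR-106b-3p -0.019 to 0.29, miR-93-5p -0.26 to 0.15, miR-93-3p -0.22 to 0.31, miR-21a-5p -0.24 to 0.28, miR-146a-5p -0.26 to 0.067, miR-30d-5p -0.23 to 0.083, miR-29a-3p -0.14 to 0.071, miR-22-3p -0.21 to 0.16, miR-191-5p -0.63 to 0.38, miR-122-5p -2.06 to 0.84, miR-31-5p -2.77 to 0.057, miR-200c-3p -0.62 to 0.13, miR-143-3p -0.088 to 0.49, miR-532-3p -0.55 to 0.13, miR-223-5p -0.48 to 0.21, miR-206-3p -0.11 to 2.75, miR-133a-3p -1.09 to 0.74, miR-192-5p -1.13 to 0.32, miR-152-3p -0.021 to 0.23, miR-451a -0.65 to 0.44, miR-486a-5p -0.26 to 0.36, miR-342-3p -0.69 to 0.14, miR-181a-5p -0.27 to 0.12 and miR-223-3p -0.23 to 0.36. The miR-34a-5p log2 difference ranged from -0.061 to 0.69 and the let-7f-5p log2 difference from -0.026 to 0.55. Between the number ranges, the log2 values that turned with 1 library left out were miR-126a-3p -0.12 to 0.12, miR-1a-3p -0.78 to 2.06 and let-7i-5p -0.16 to 0.20. The cause was not tested. In simulated data for this comparison 0% of 2-fold changes and 23% of 4-fold changes were recovered without the number range block, and 15% and 58% with it, which limits what 0 calls can exclude.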

Other observations

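The comparison of animal number ranges, its tests and its named miRNAs were chosen only after the grouping of the libraries had been seen, though the 2 ranges had been set from the labels before the data were examined, and the test of sequence ends was added after the tests of GC content and depth.

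Libraries of animals 35 to 46 and of animals 80 to 90 had different miRNA profiles. In edgeR with genotype as the other term, 99 of 627 entries were higher and 104 lower in the low-numbered animals at an adjusted p of 0.05, and DESeq2 called 276. Of 20 entries of the let-7 family, 9 were called lower in the low-numbered animals and 1 higher (median log2 difference -0.87, camera adjusted p 0.00455). Of the 9, let-7a-5p and let-7c-5p_1ss19GA share 1 sequence and its values. The list's call was lost with an estimated correlation (adjusted p = 0.9998 with an estimated correlation). For let-7d-5p, the level was 2585 ± 603 CPM in the low-numbered and 14216 ± 2724 CPM in the high-numbered animals (SD, n = 4 each). For let-7a-5p, it was 2422 ± 532.3 and 11091 ± 2280 CPM. The 3p arm let-7i-3p rose 6.34-fold, while let-7i-5p differed by 0.04 on the log2 scale and was not called.

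Both arms of miR-21a were higher in the low-numbered animals: miR-21a-3p was 1056 ± 299.2 CPM in the low-numbered and 152.2 ± 19.9 CPM in the high-numbered animals (SD, n = 4 each; 6.95-fold), and miR-21a-5p was 350582 ± 69162 and 192741 ± 51924 CPM (1.82-fold, edgeR adjusted p 0.0296), a call that stayed in 1 of 8 fits with 1 library left out. The difference between the arms was not tested. Markers of other cell types were among the calls. The hepatocyte miR-122-5p was 42085 ± 50134 CPM in the low-numbered and 6816 ± 1671 CPM in the high-numbered animals (5.44-fold, edgeR adjusted p 0.0243), but 2.25-fold without wild-type library 37 (edgeR adjusted p 0.135). The hepatocyte list as a whole did not differ past the threshold, with 1 member called higher and miR-455-3p called lower (camera adjusted p 0.996). The erythroid miR-451a rose 9.97-fold in the low-numbered animals, miR-378a-3p, encoded in an intron of Ppargc1b, rose 2.65-fold, and miR-34a-5p, a p53-responsive miRNA, had a level of 160 ± 26.3 against 39.7 ± 10.5 CPM. In the other direction, miR-455-3p fell from 656 ± 128.4 to 72.5 ± 7.18 CPM and miR-191-5p from 47150 ± 12224 to 12364 ± 2674 CPM. Without wild-type library 37, 129 entries were called.

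The count of 0 genotype calls says nothing about chance, since any split gives at least 0, as 35 of 35 did. The highest of the others, 227, was the split by number range, which pointed to a structure of the samples. By unadjusted p under 0.05, 31 of the 35 splits gave as many entries as the real 2, with 295 the highest of the others, so chance could not be excluded for these. For the number ranges, 1 of 35 splits, the real one, reached the 227 calls of a fit without genotype, and the highest of the others was 0. That is the smallest share that 35 splits allow. Each other split has animals of both ranges on a side, so the range difference widens the spread within its groups and makes calls unlikely. The split count alone therefore does not exclude chance.

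Tests of GC content and length, of the terminal bases and of depth argue against each as the whole cause of the number range difference. After the GC and length trend of each library was removed, 80.16% of the 247 limma calls stayed with their sign. After the effects of the first and last 2 bases were removed, 77.33% stayed. Those bases accounted for 6.29% of the variation of the range difference (adjusted R squared), so their removal could change little. Adapter ligation preferences that do not depend on those bases were not tested. With each library thinned to the total of the smallest the calls were 113.3% of those before, at 230 among 547 tested entries. A lower share of Kupffer cells in the sorts of the low-numbered animals stays open: of 13 markers of other cell types outside the myeloid list, 5 were called higher there (miR-122-5p, miR-451a, miR-486a-5p, miR-143-3p and miR-133a-3p) and 1 lower (miR-200c-3p, at a log2 difference of -1.278), too few called lower to exclude it. The 2 markers left out, miR-342-3p (-1.47) and miR-223-3p (-1.01), were both called lower. With them the rule of at least 2 called each way would have argued against a lower share. The outcome thus depended on leaving them out. As they also stand in the myeloid list, a lower share of Kupffer cells could lower them too. The myeloid list as a whole did not fall, however. In the low-numbered animals 6 of its members were called higher and 5 lower (median log2 difference 0.31, camera adjusted p 0.940). Of the 13 markers 7 were not called, among them the endothelial miR-126a-3p at a log2 difference of 0.01. The miR-122-5p call stayed in 4 of 8 fits with 1 library left out. Litter, a day of sorting or a batch may lie behind the number ranges. None of these and no biological explanation was tested, since the labels do not say what the numbers mark.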
